A study of Homo sapiens with 4 samples.

How the data were processed

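The series holds 4 polyA RNA sequencing libraries from HCT116 cells, an established human colorectal carcinoma line. Per the labels' protocols, the cells were stably transduced with a pSin lentivirus that was empty (2 libraries) or carried the full-length coding sequence of FOXD2, a forkhead transcription factor (2 libraries), and were kept under puromycin selection. RNA was extracted with TRIzol, and libraries were made with a strand-specific NEBNext kit after magnetic isolation of mRNA, per the labels' protocols. The chromatin and chromosome-contact assays that the series' design text names were not analysed here.

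Each library came as a table of genes with effective lengths. Per the submitters' processing notes, STAR 2.7.2b and RSEM 1.2.31 were used with the GRCh38 (hg38) genome; the notes as used here give neither the annotation release nor the strand setting of the counting. The authors' tables give, per the file headers, the RSEM expected count of each gene, an estimate that shares reads mapping to several genes among them and so need not be whole. The tables also give, per the file headers, the authors' TPM, which was used for an alternative test, and the authors' FPKM, which was not tested. Reads of near-identical genes (KRT6A, KRT6B and KRT6C, or HBA1 and HBA2) are divided by the estimate of RSEM, so values of single members of such families are uncertain. Values of genes that overlap another gene, or lie antisense to one, are uncertain too, because the strand setting is not stated. The counts of FOXD2 pool the delivered coding sequence with the transcript of the cells' own gene.

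Of the 60683 gene identifiers, 60370 were matched to a symbol and 58496 to GENCODE release 29 on GRCh38, from which coordinates and gene classes were taken. The authors' annotation was another one in part, since FOXD2 has a length of 2648 bases in the files and spans 4675 bases in release 29. All rows of the tables name a gene.

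Expected counts were rounded to whole numbers. Totals were 14245777 and 15535817 in empty vector replicates 1 and 2, and 15340166 and 14231338 in FOXD2 replicates 1 and 2. A count of 0 allows a level of up to 3 counts, which was between 0.193 and 0.211 CPM, the count relative to library size, in these libraries. Such limits and intervals cover counting error only, as reads without molecular identifiers are not independent molecules. Replicates were compared before use: the chi-square statistic per degree of freedom was 2.52 between the empty vector libraries and 3.91 between the FOXD2 libraries, so no pair agreed within sampling noise, and it lay between 50.3 and 54.1 across groups. The labels do not say whether replicates came from separate cultures or transductions, so p-values measure the spread between these samples, which may be technical.

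Groups and gene lists were taken from the labels and from textbook knowledge before the data were examined, as were the tests, the rule for naming genes and the alternatives, except those said below to have been chosen later. FOXD2 libraries were compared with empty vector libraries by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust fit, intercept and group, both directions tested). Adjusted p-values of genes are from this test with Benjamini-Hochberg adjustment over the 14470 genes that passed the filter, at a threshold of 0.05. CPM values use TMM-scaled library sizes and are given as mean ± SD with n = 2 per group. Fold changes are the fitted log2 ratios of FOXD2 to empty vector with a standard error (SE). Where a group held 1 to 3 counts in all, the ratio of counts is given with an exact 95% interval, and where it held 0, a lower bound against 3 counts over the group.

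The 26 gene lists were Wnt targets, epithelial junction and keratin, mesenchymal and EMT, enterocyte and colonocyte, secretory lineage, cell cycle, p53 targets, interferon response, NF-kB and cytokine, immediate early and AP-1, MAPK feedback, YAP and TEAD targets, TGF-beta and BMP, Notch pathway, hypoxia, integrated stress and unfolded protein, cholesterol synthesis, H3K4 methyltransferase and enhancer cofactors, forkhead family, HOX clusters, axon guidance and neuronal, markers of fibroblasts, of blood and endothelium and of packaging cells, mitochondrial mRNAs, and replication-dependent histones. The 23 lists with at least 5 tested genes were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over these lists. The test was repeated with the correlation estimated from the data, and fry gave a test of each list by itself. The repeat rests on the few residual degrees of freedom of 4 libraries, so its p-values also rise for a reason other than correlation.

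Genes were named by rule: FOXD2 and FOXD2-AS1; the 10 largest rises and the 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1, no overlap between groups and a proper symbol; the 5 smallest p-values in each direction; and up to 4 members of smallest p from each list. Other genes are named to describe a list or region and were chosen after their values were seen. A few genes that the rule takes are not reported here.

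The edgeR and camera steps were tested on simulated counts with the means of the empty vector libraries and the library sizes of all samples. Of 50 genes changed at each size, 32% were recovered at 1.25-fold, 70% at 1.5-fold, 82% at 2-fold and 96% at 4-fold, untested genes counted as not recovered. Of 14470 simulated genes 13940 passed the filter, and 13 of the 13745 unchanged genes among them were called. Of simulated lists of 20 genes, 10 of 10 changed by 1.5-fold and 1 of 10 unchanged were called with the preset correlation, and 10 of 10 and 0 of 10 with an estimated correlation. Genes were simulated independently of each other. Far fewer were changed than passed the threshold in the data, so recovery and false calls may differ there.

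Alternatives were RLE size factors, upper-quartile factors, FOXD2 left out of library sizes, no filter on low counts, a filter of 1 CPM in 2 libraries, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1, and glmTreat against a fold of 1.2. Chosen after seeing the data were library sizes without scaling factors, removal of mitochondrial, histone and structured RNAs, and removal of a smooth trend on gene length and GC content. The lists of keratinocyte genes, the counts by gene family and the windows of neighbouring genes in the closing section were also chosen after seeing the data.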

Results

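RNA was measured in HCT116 colorectal carcinoma cells carrying FOXD2 or an empty lentiviral vector, with 2 libraries in each group, to survey transcription in the presence of FOXD2. Between 14231338 and 15535817 counts were assigned to genes per library. At least 10 counts were found for 14003 and 14093 genes in the empty vector libraries and for 14507 genes in each FOXD2 library. The first principal component held 83.9% of the variance.

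FOXD2 itself was measured first, as a check of the labels. It rose from 3.14 ± 0.511 CPM in empty vector cells to 502.8 ± 33.5 CPM in FOXD2 cells (SD, n = 2 each), a log2 fold change of 7.32 (SE 0.10, edgeR adjusted p = 6.5e-50). Counts were 49 and 42 in the empty vector libraries, so the gene was detectable at a low level in cells with the empty vector. The gene lies on chromosome 1 from 47436017 to 47440691, plus strand, GRCh38, as 1 exon whose coding part, the part delivered by the virus, runs from 47438136 to 47439620. The neighbouring antisense long noncoding RNA FOXD2-AS1 (chromosome 1, 47432133 to 47434641, minus strand) had a log2 fold change of -0.56 (SE 0.25) and did not pass the threshold (edgeR adjusted p = 0.058). It passed (adjusted p = 0.013) only when a trend on gene length and GC content was removed.

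The transcriptome was then compared between FOXD2 and empty vector cells. Keratin and epidermal genes were among the largest rises, together with the signalling ligand SHH, the forkhead gene FOXQ1 and the chemokine receptor CXCR4, whereas the receptor tyrosine kinase MET, the EGF family ligand EREG and the KIT ligand KITLG were among the genes that fell most or with the smallest p. Of 14470 genes tested, 3929 were higher and 3816 lower in FOXD2 cells (edgeR adjusted p under 0.05), which is 53.5% of them. At least 2-fold differences were found for 1186 higher and 405 lower genes, and fitted differences over 10-fold for 108 higher and 7 lower genes. Of the genes past the threshold, 57.6% differed by less than 1.5-fold. The biological coefficient of variation was 4.99%, so that small differences passed. DESeq2 placed 2414 genes higher and 2801 lower.

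**Figure D1:**
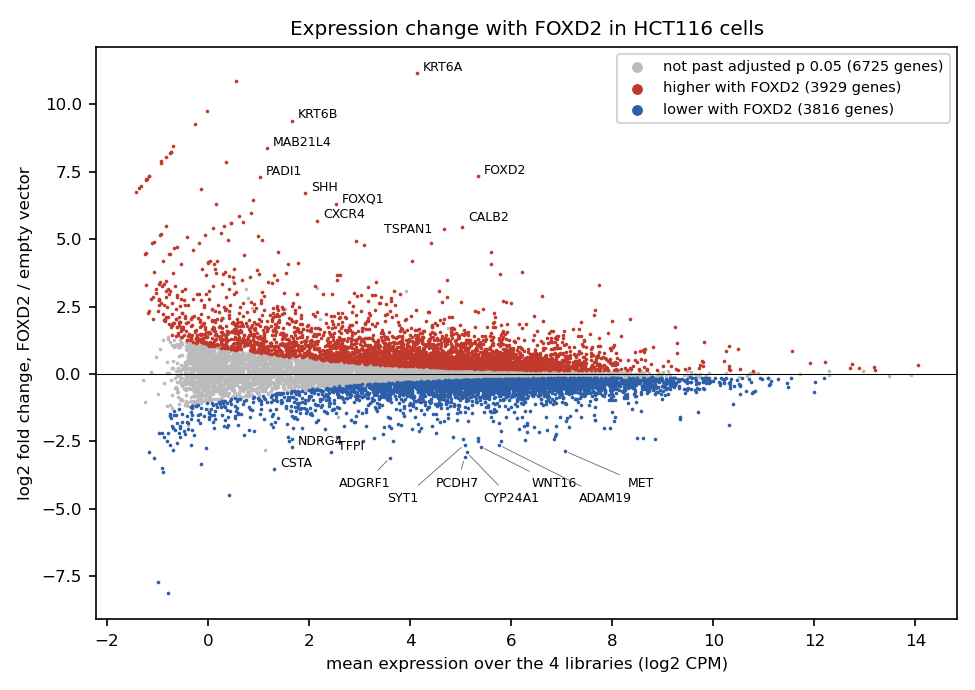
Log2 fold change of FOXD2 over empty vector (vertical) against mean expression in log2 CPM (horizontal); each point is 1 of the 14470 genes tested, red for the 3929 higher and blue for the 3816 lower genes at edgeR adjusted p under 0.05. The 10 largest rises and falls chosen by rule are named, from KRT6A at 11.16 to CSTA at -3.52.

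KRT6A, a keratin of hyperproliferative epidermis and of epithelia such as the tongue, showed the largest rise, from 0.306 ± 0.129 to 725.9 ± 195.1 CPM (log2 fold change 11.16, SE 0.62, edgeR adjusted p = 0.0045). With empty vector replicate 1 or 2 left out its adjusted p was 0.11 or 0.12, and with limma-voom 0.063, while its log2 fold change stayed between 10.80 and 11.66 with these libraries left out. Its near-identical neighbour KRT6B had 2 counts, all in replicate 1, in the empty vector libraries and 1576 in the FOXD2 libraries, a ratio of 759 (95% interval 210 to 6270), and the pair may share reads. Both lie in the type II keratin cluster of chromosome 12. KRT80, another type II keratin, rose from 10.1 ± 0.959 to 231.3 ± 6.25 CPM. The peptidylarginine deiminase PADI1 had 3 counts in empty vector cells and 527 in FOXD2 cells, a ratio of 169 (interval 57.6 to 823), and MAB21L4 had 2, all in empty vector replicate 1, and 782, a ratio of 376 (interval 104 to 3114).

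Other large rises included some signalling and surface genes. SHH, a hedgehog ligand, rose from 0.334 ± 0.371 to 37.0 ± 0.964 CPM (log2 fold change 6.71, SE 0.24), with 1 and 9 counts in the empty vector libraries. Its fitted log2 fold change was 5.93 without empty vector replicate 1 and 8.85 without replicate 2, the latter against a single count. CXCR4 rose from 0.554 ± 0.127 to 28.8 ± 1.63 CPM (5.69, SE 0.22). The calcium-binding protein gene CALB2 rose by 5.43 on the log2 scale (SE 0.10) and the tetraspanin TSPAN1 from 3.89 ± 0.0325 to 162.4 ± 0.199 CPM. Their edgeR adjusted p-values were at most 7.9e-27.

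Among genes that fell, MET went from 358.0 ± 29.9 to 49.5 ± 2.21 CPM (log2 fold change -2.85, SE 0.07, edgeR adjusted p = 3.2e-37). EREG, which encodes the EGF receptor ligand epiregulin, went from 813.9 ± 0.314 to 157.5 ± 3.81 CPM (-2.37, SE 0.06), KITLG from 1063 ± 62.3 to 200.7 ± 12.2 CPM (-2.40, SE 0.06), and DCBLD2 from 890.4 ± 45.6 to 172.5 ± 7.52 CPM (-2.37, SE 0.06). The protein kinase A scaffold AKAP12 went from 2469 ± 104.3 to 661.3 ± 16.5 CPM (-1.90, SE 0.05). CSTA, a cysteine protease inhibitor of the cornified envelope, fell by 3.52 on the log2 scale (SE 0.30), against the direction of the keratins. The other large falls were ADGRF1 (-3.10), the protocadherin PCDH7 (-3.09), the vitamin D hydroxylase CYP24A1 (-2.90), the coagulation inhibitor TFPI (-2.89), NDRG4 (-2.69), WNT16 (-2.69), ADAM19 (-2.63) and the synaptic gene SYT1 (-2.62), with edgeR adjusted p at most 1.4e-12.

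**Figure D2:**
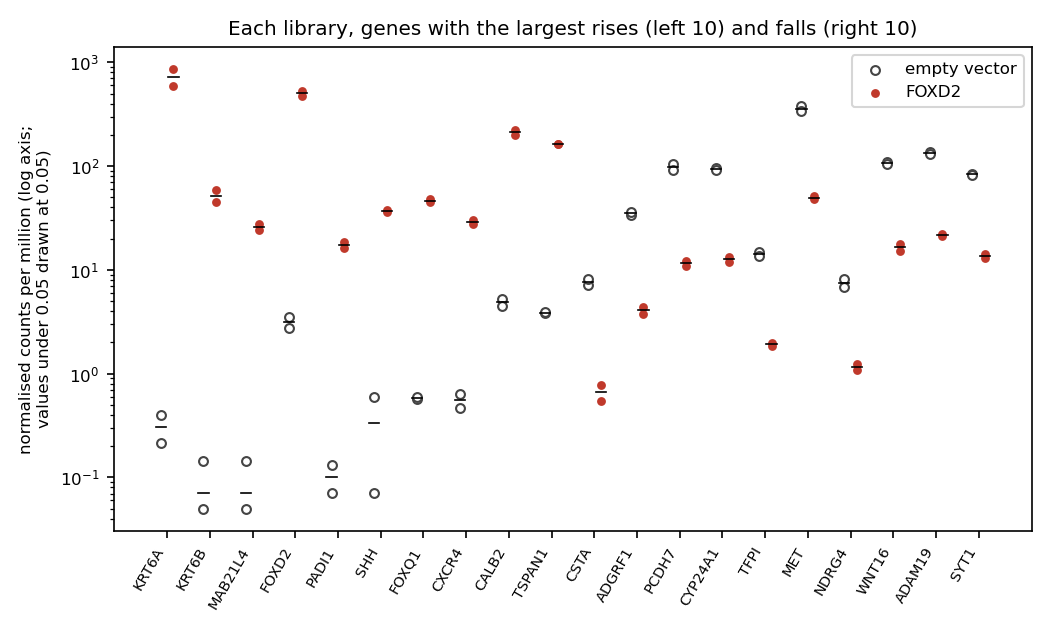
Normalised read counts (CPM) on a log axis for each library (open circles, 2 empty vector; filled circles, 2 FOXD2) of the 10 genes with the largest rises and the 10 with the largest falls, with horizontal bars at the group means and values under 0.05 drawn at 0.05. The FOXD2 libraries lie above both empty vector libraries for the rises, as for FOXD2 itself (479.1 and 526.5 CPM against 2.78 and 3.50), and below them for the falls.

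Epithelial genes rose as a group. Of 23 tested genes for epithelial junctions and simple keratins, 18 rose and 2 fell (median log2 fold change 0.77, camera adjusted p = 5.7e-05; adjusted p = 0.42 with an estimated correlation). The tight junction genes CLDN4 (129.0 ± 16.9 to 507.4 ± 1.47 CPM, log2 fold change 1.98) and CGN (1.94) rose, as did E-cadherin CDH1 (1.09), KRT19 (1.04) and KRT8 (0.85). ELF3 and ESRP1, an epithelial transcription factor and a splicing regulator, fell by 0.38 and 0.29. Of 12 mesenchymal genes 7 rose and 2 fell (median 0.44), but the list did not pass (camera adjusted p = 0.080), except without empty vector replicate 2 (adjusted p = 0.047), with a filter of 1 CPM (0.032) or with limma-voom (0.014). TNC (5.10), THBS1 (3.48) and the EMT factor SNAI2 (3.04) rose and TWIST1 fell by 1.51. The levels of SNAI2 (0.441 ± 0.219 to 3.74 ± 0.165 CPM) and TWIST1 (0.862 ± 0.0954 to 0.293 ± 0.221 CPM) were low. The value for VIM was -0.16 and did not pass. Of markers of other cell types, the fibroblast genes COL1A1 (1.68) and ACTA2 (1.10), the only 2 tested of their list, rose, to 32.1 ± 0.979 and 8.45 ± 1.22 CPM.

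Cell cycle genes fell. Of 25 tested, 24 were lower and none was higher (median log2 fold change -0.54, camera adjusted p = 2.9e-08; adjusted p = 0.42 with an estimated correlation), and the exception, CCNE2, had a value near 0. The replication licensing gene MCM2 went from 301.8 ± 3.87 to 171.4 ± 2.93 CPM (-0.82, SE 0.06), and the mitotic gene CENPF (-0.73), MCM4 (-0.66) and MCM3 (-0.64) also fell. Of 22 p53 targets, 16 were higher and 0 lower (median 0.39, camera adjusted p = 0.00011; adjusted p = 0.49 with an estimated correlation). They included the CDK inhibitor CDKN1A (1.43), the stress cytokine GDF15 (2.39), TP53INP1 (1.21), PLK3 (1.03), TP53I3 (0.99) and TNFRSF10B (0.46).

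Interferon-response genes had the highest median of the tested lists after the histones. Of 26 tested, 23 rose and 1, HERC5, fell (median 1.61, camera adjusted p = 2.0e-08; adjusted p = 0.49 with an estimated correlation). The regulators IRF7 (3.95 ± 0.0288 to 28.3 ± 3.11 CPM, log2 fold change 2.84, SE 0.15), IRF9 (2.80, SE 0.14) and STAT2 (1.47, SE 0.10) rose, with the effectors ISG15 (1.51) and MX1 (2.78). OAS1 had 3 counts in the empty vector libraries and 96 in the FOXD2 libraries, a ratio of 30.8 (interval 10.2 to 152.0), and the list's median was the same with this gene at its bound. The summed CPM of the list was 401.1 and 385.1 in the empty vector libraries and 812.3 and 1030 in the FOXD2 libraries. Of blood and endothelial markers, of which 4 were tested, the macrophage and lysosome gene CD68 rose (2.98), and HBA2 was at least 13.2-fold higher against 0 counts in empty vector cells. HBA2 may share reads with HBA1 (1.03 ± 0.139 and 0.675 ± 0.954 CPM), and the pair together had 1.03 ± 0.139 CPM in empty vector cells and 2.04 ± 0.660 CPM in FOXD2 cells.

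Several signalling lists were higher. Of 14 NF-kB and cytokine genes, 9 rose and 1 fell (median 0.59, camera adjusted p = 0.0040; adjusted p = 0.42 with an estimated correlation), among them the feedback inhibitor TNFAIP3 (2.65), BIRC3 (1.63), RELB (1.05) and LIF (0.85). Of 17 immediate early genes, 12 rose and 0 fell (median 0.39, camera adjusted p = 0.00052; adjusted p = 0.42 with an estimated correlation). JUN went from 15.1 ± 0.627 to 198.3 ± 7.74 CPM (3.71, SE 0.08), NR4A1 rose by 1.71, EGR1 by 0.76 and IER3 by 0.55, while FOS (0.26) did not pass. Of 19 YAP and TEAD targets, 14 rose and 3 fell (median 0.41, camera adjusted p = 0.016; adjusted p = 0.42 with an estimated correlation), with CCN2 at 4.80, AMOTL2 at 1.32, LATS2 at 1.11 and MYOF at 0.78, and TGFB2 fell by 1.91. Of 16 Wnt targets, 10 rose and 3 fell (median 0.74, camera adjusted p = 0.0080; adjusted p = 0.42 with an estimated correlation). The Wnt feedback inhibitors NKD1 (1.75) and RNF43 (1.42) rose, as did CCND1 (600.3 ± 22.8 to 1350 ± 64.0 CPM, 1.17), whereas the effector TCF7L2 fell by 1.37 and the inhibitor DKK1 by 1.41.

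The integrated stress and unfolded protein list was lower, with 12 of 23 genes down and 6 up (median -0.37, camera adjusted p = 0.014; adjusted p = 0.74 with an estimated correlation). PHGDH (180.6 ± 10.9 to 33.1 ± 1.37 CPM, -2.45, SE 0.08) and PSAT1 (-1.70), which act in serine synthesis, ASNS (-1.95), which makes asparagine, and CHAC1 (-1.71), which degrades glutathione, fell most. PCK2, the mitochondrial PEP carboxykinase, fell by 1.40. Genes of the endoplasmic reticulum went both ways: XBP1 (0.34), DNAJB9 (0.42), HERPUD1 (0.29) and CALR (0.21) rose, the chaperones HSPA5 (-0.34) and HSP90B1 (-0.15) fell, and SDF2L1 (-0.20) did not pass.

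**Figure D3:**
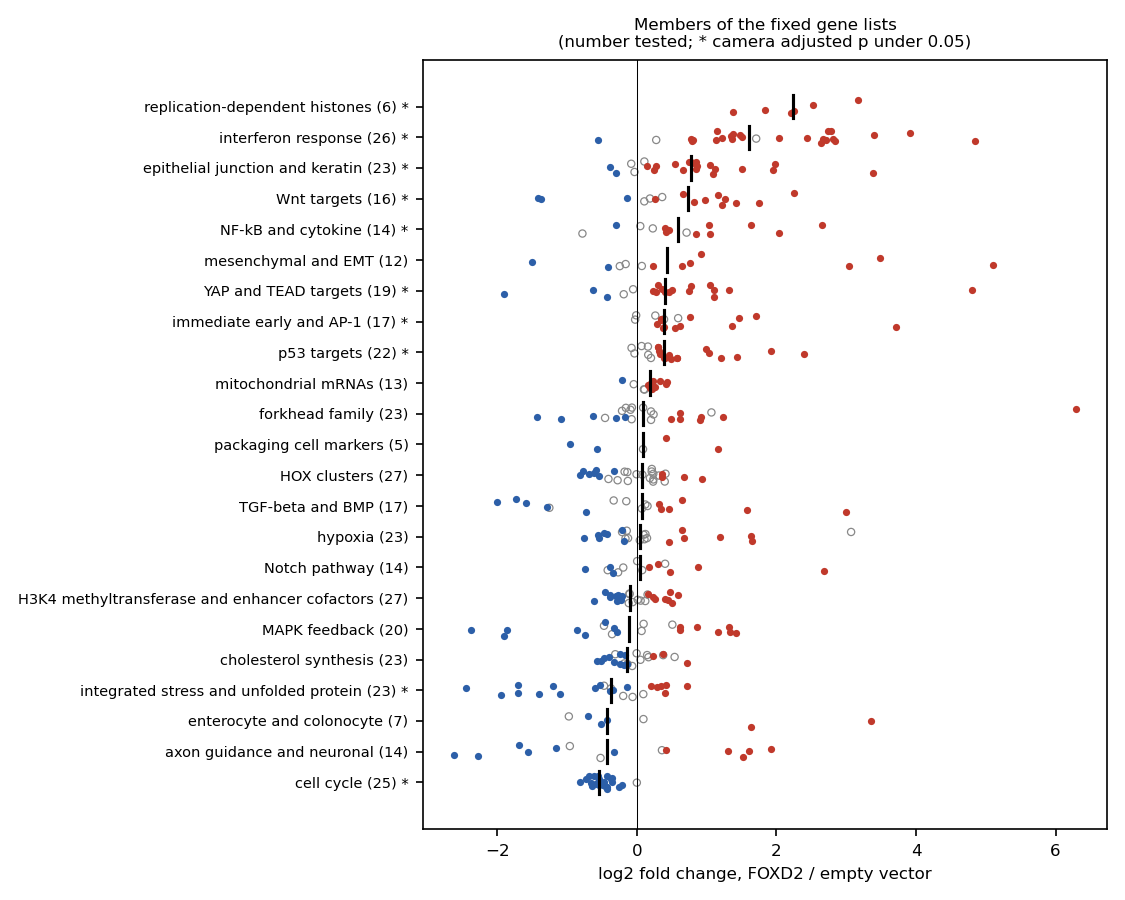
Log2 fold change of FOXD2 over empty vector for each member (points) of the 23 lists tested, with the number of tested genes in brackets, an asterisk for camera adjusted p under 0.05 and a bar at the median; red and blue points passed edgeR adjusted p under 0.05 and open points did not. Interferon-response genes centre at 1.61 and cell cycle genes at -0.54.

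The other lists were not placed higher or lower by camera, and many held large changes in both directions. Of 20 MAPK feedback genes 7 rose and 8 fell (median -0.11, camera adjusted p = 0.81), with SPRY4 (1.33) and MYEOV (1.42) up and EREG down. Of 17 TGF-beta and BMP genes 6 rose and 5 fell (median 0.07, mean -0.14, adjusted p = 0.71). The BMP targets ID1 (-1.74), ID2 (-1.59) and ID3 (-1.29) fell, as did the receptor TGFBR2 (36.8 ± 0.632 to 9.15 ± 0.771 CPM), and LTBP2 rose by 1.57. Of 14 Notch genes 5 rose and 3 fell (median 0.04, adjusted p = 0.75), with HES1 going from 23.4 ± 0.577 to 150.7 ± 2.50 CPM (2.68, SE 0.08), NOTCH3 at 0.87, NRARP at -0.74 and NOTCH2 at -0.38. Of 14 axon guidance and neuronal genes 5 rose and 6 fell (median -0.43, adjusted p = 0.37), with L1CAM at 1.60, SEMA3C at -1.55 and EFNB2 at -1.16. Of 23 forkhead genes other than FOXD2, 7 rose and 5 fell (median 0.09, adjusted p = 0.75). FOXQ1 went from 0.584 ± 0.0170 to 46.4 ± 2.0 CPM (6.29, SE 0.19), FOXO4 rose by 0.92 and FOXO3 by 0.61, and FOXC1 fell by 1.43.

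Of 27 genes in the list of H3K4 methyltransferases and enhancer cofactors, 8 rose and 11 fell (median -0.11, camera adjusted p = 0.71). They included the H3K4 demethylases KDM1A (-0.62) and KDM5C (0.45), the cohesin gene RAD21 (-0.46) and the methyltransferase SETD1B (0.51). Of 27 HOX genes 4 rose and 7 fell (median 0.08, mean -0.02, adjusted p = 0.75), with HOXB4 at -0.82, HOXB8 at -0.77, HOXA10 at -0.62 and HOXA9 at -0.55. Of 23 hypoxia genes 6 rose and 7 fell (median 0.04, mean 0.26, adjusted p = 0.95), with EGLN3 at 1.65, KISS1R at 1.63, BNIP3 at -0.76 and ENO1 at -0.42. Of 23 cholesterol synthesis genes 3 rose and 10 fell (median -0.14, adjusted p = 0.42). Among them SQLE (-0.52) and TMEM97 (-0.46) fell. Without FOXD2 replicate 2 this list passed as lower (adjusted p = 0.037). Of 7 enterocyte genes 2 rose and 3 fell (median -0.42, mean 0.35, adjusted p = 0.74). The mucin MUC13 rose by 3.36, and CA2 (-0.70), the intestinal factor CDX2 (-0.51) and KLF4 (-0.42) fell. CDX2 did not pass without empty vector replicate 2 (adjusted p = 0.056), nor did CDX2, KLF4 or NOTCH2 with limma on TPM. Of 3 secretory lineage genes MUC1 rose (1.94). Of 5 packaging cell markers, for carry-over from virus production, 2 rose and 2 fell (median 0.09, mean 0.03, adjusted p = 0.95), with VGF at 1.16, PAX2 at 0.42 and ZIC2 at -0.57. The PAX2 call ended without empty vector replicate 1 (adjusted p = 0.16), empty vector replicate 2 (0.061) or FOXD2 replicate 2 (0.096). For the TGF-beta, hypoxia, HOX, enterocyte and packaging cell lists the camera direction was down, opposite to the median, the mean or both.

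Of the 60 genes of the replication-dependent histone list only 6 were tested, and all 6 rose (median 2.24, camera adjusted p = 0.0014, and 0.42 with an estimated correlation). Among them were H1-2 (5.34 ± 0.533 to 24.8 ± 3.42 CPM, 2.21), H2AC6 (2.52), H2BC5 (2.26) and H3C10 (1.84). The median was the same with H2BC11, which had 3 counts in empty vector cells, at its bound. Of 13 mitochondrial mRNAs 9 rose and 1 fell (median 0.18, camera adjusted p = 0.072, and 0.0016 with limma-voom), with MT-CYB at 0.43, MT-ND5 at 0.42, MT-CO1 at 0.34 and MT-CO3 at 0.25. Mitochondrial mRNAs made up 6.79% and 6.80% of counts in the empty vector libraries and 8.17% and 8.62% in the FOXD2 libraries. RNAs made without a polyA tail, such as RN7SL1 and RN7SK, summed to 31.6 and 29.8 CPM in empty vector cells and to 134.1 and 60.6 CPM in FOXD2 replicates 1 and 2, so that FOXD2 replicate 1 stood apart in this class.

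Counts of list members adjusted over the list alone were 12 higher and 3 lower for Wnt targets, 17 and 0 for p53 targets, 24 and 1 for interferon response, 14 and 4 for YAP and TEAD targets, and 6 and 14 for integrated stress. They were 2 and 4 for enterocyte genes, 7 and 7 for hypoxia, 9 and 11 for H3K4 methyltransferases and cofactors, and 10 and 1 for mitochondrial mRNAs. For the other lists they equalled the counts adjusted over all genes. The camera calls of all 10 lists were lost with an estimated correlation. For the Wnt, epithelial, and YAP and TEAD lists that estimate (-0.048, -0.0094 and -0.055) lay below the preset 0.01. A higher correlation between members thus cannot explain the loss in these lists. With an estimated correlation, camera also relies on the few residual degrees of freedom of 4 libraries, which it does not with a preset one. This raises the p-values of all 10 lists, so a lost call does not by itself show correlation between members. How much each adds was not tested. With fry, which tests a list by itself, 12 lists were higher and 4 lower at adjusted p under 0.05. Such a test passes easily where 53.5% of all genes passed. The fry test for changes in either direction passed for every list tested (largest adjusted p = 0.014, HOX clusters).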

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

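Removal of scaling factors, of RNA classes and of the length and GC trend were tests chosen after the data were seen. FOXD2 rose under each alternative run for it (not glmTreat), by 6.67 to 7.49 on the log2 scale. Leaving out 1 library, where the lone sample of its group is assumed to vary like the other group, gave 3146 to 3579 higher and 3046 to 3650 lower genes, with 1114 to 1183 higher and 376 to 471 lower by at least 2-fold, and 8 to 9 lists called higher and 2 to 3 lower. Counts moved by over 1.5-fold with DESeq2 (2414 higher), with limma on log2(TPM + 1) (2330 lower, 718 at least 2-fold higher, 232 at least 2-fold lower) and on log2(TPM + 0.1) (2327 lower), and with glmTreat (2551 higher, 1916 lower), which by construction drops small differences; for the others the cause was not tested. Camera with an estimated correlation called 0 lists higher and 0 lower, with or without the replicate block, and fry called 4 lower. The replicate number as a block gave 3680 higher and 3494 lower genes and changed no other call; same-numbered libraries did not deviate together (correlation across genes -0.099), so the numbers were not taken to pair the samples. Among 2015 values of the 119 named genes besides FOXD2 over 17 alternatives, 1995 kept direction and side of the threshold, 19 fell short of it (6 genes, among them KRT6A, KLF4, CDX2, NOTCH2 and PAX2), 1 passed it (FOXD2-AS1) and 0 reversed. The depth leaves levels under about 0.2 CPM undetected.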

Other observations

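All gene groups and windows below, and the comparison of detected genes, were tests chosen after the data were seen. Grouped by the start of their symbol, 3 of 222 families held more genes at least 2-fold higher than the background share of 975 of 12698 genes (one-sided Fisher's exact test, Benjamini-Hochberg adjusted over both directions). They were keratins (13 of 21, adjusted p = 1.5e-07), kallikrein proteases (7 of 8, adjusted p = 2.6e-05) and collagens (9 of 19, adjusted p = 0.00060). The keratins included KRT7 (68.2 to 666.7 CPM, log2 fold change 3.29), KRT15 (12.7 to 81.6 CPM, 2.69), KRT81 (2.94) and KRT16 (5.22), while KRT10, a keratin of suprabasal epidermis, fell by 0.37. The kallikreins KLK6 (41.7 to 185.8 CPM, 2.15) and KLK7 (23.1 to 110.2 CPM, 2.25), which cleave junction proteins in skin, rose. Among collagens, COL17A1 and COL7A1, which anchor epidermis to its basement membrane, rose by 2.94 and 1.71, and COL12A1 fell by 0.94 from 133.1 CPM. Of the 56 genes of the cornification list 34 were tested, of which 27 rose and 4 fell (median 1.69, camera p = 2.3e-07, p = 0.027 with an estimated correlation). The median was the same with its 6 members of 3 or fewer control counts at their bounds. These 6 passed the filter on low counts through the FOXD2 libraries, so the tested genes lean toward rises. This list holds KRT6A, KRT6B, KRT80 and PADI1, named above as rises, and CSTA, named as a fall. Its p-values thus partly restate changes seen before the list was chosen. RPTN, a cornified envelope gene, was at least 154-fold higher against 0 control counts, and SLPI rose by 4.51. Of 12 tested markers of basal keratinocytes 10 rose and 2 fell (median 1.01, camera p = 0.0016, p = 0.12 with an estimated correlation).

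Neighbouring genes moved together at a few places. Of all windows of 20 neighbouring tested genes, 9 that did not overlap had a median log2 fold change past 0.76, the 95th percentile of the largest median in 1000 shuffles of gene order. The largest were on chromosome 12 from 51906908 to 53180909, with the type II keratins (median 1.31, 15 genes higher and 2 lower), on chromosome 17 from 40388516 to 41615899, with type I keratins (1.247, 12 and 4), and on chromosome 1 from 151770107 to 153631360, where FLG, IVL, RPTN and S100 genes lie (1.11, 17 and 0). These 3 also exceeded the largest shuffled value, 1.06, and their medians did not move with low-count genes at their bounds. The only window that fell was on chromosome 12 from 72253508 to 80937925 (-0.82, 1 and 15), with SYT1 at -2.62 and PHLDA1 at -0.86. Others included chromosome 11 from 289135 to 727727, with IFITM genes and IRF7 (0.83, 15 and 1), and chromosome 6 from 25992662 to 27146798, with histone and butyrophilin genes (0.82, 12 and 3). Related genes lie side by side in most of these windows, so their members are not independent.

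The squamous pattern was weighed against an admixture of keratinocyte-type cells and against shared reads. If keratinocyte-type cells had been mixed in, most basal markers would rise, as 10 of 12 did, KRT14 among them (2.03), but KRT5 and KRT14, abundant in such cells, would also stand at 10% or more of KRT6A. They reached at most 0.186% of its CPM in the FOXD2 libraries, which argues against it. Reads shared within the KRT6 family do not account for the pattern either, since the cornification genes outside that family had a median of 1.41, with 25 of 32 higher and 4 lower. A response to FOXD2 remains a hypothesis, and a difference between the selected cell pools that predates or accompanies transduction may equally remain, since the labels do not give independent transductions.

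The share of genes past the threshold was weighed likewise. A copy number difference would shift long runs of neighbours alike, and 0% of tested genes lay in windows of 100 neighbours shifted by 0.4 or more. The largest shift was 0.38, on chromosome 11. Windows of this size cannot show a copy difference over fewer genes or in a part of the cells. Whether the window of 20 genes that fell on chromosome 12 (median -0.82) reflects one was not tested. Log2 fold changes rose with GC content (Spearman correlation 0.26) but hardly followed length (-0.025). Removing a trend on both kept 86.4% of calls, changed the sign of 36 and left 1048 genes at least 2-fold higher against 1186. The trend thus does not account for the whole, but a part may follow GC content. With 3 other scalings, 7618 to 7751 genes passed the threshold against 7745. The share of higher genes among calls moved by at most 8.52 percentage points. The choice among these scalings thus does not account for the whole, but all are relative to the RNA sequenced, so none could show a change in total RNA per cell. With replicates this close, differences between the cell pools other than FOXD2 may also pass, which the design leaves untested.

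Histone mRNAs, the sum of the structured RNAs and most mitochondrial mRNAs were higher in FOXD2 libraries. Fewer reads in nuclear genes would lower the number of detected genes, but each FOXD2 library had 14507 with at least 10 counts, above both empty vector libraries. Genes that rose would also raise this number, so it does not decide the question. Histone mRNAs as a class lack a polyA tail, but whether the counted reads came from forms with a tail was not tested. For these mRNAs, carry-over of untailed RNA cannot be told apart from a change in the cells or from such forms. Structured RNAs were 3.17-fold higher on average, but FOXD2 replicate 1 exceeded replicate 2 by 2.21-fold in them and by 1.21-fold in histone mRNAs. A cause in FOXD2 replicate 1 alone does not account for the histone rise, since replicate 2 had 56.1 CPM against 13.02 and 13.18 in empty vector cells; its structured RNAs summed to 60.6 CPM against 31.6 and 29.8, with RN7SL1, RN7SL2, RPPH1 and RN7SK above both empty vector libraries and RMRP between them. For the mitochondrial mRNAs carry-over cannot be told apart either, because the histone median (2.24 against 0.18) has no settled cause, MT-ND6 fell by 0.21, the mitochondrial rRNAs differed (MT-RNR1 5685 and 6465 CPM in empty vector and 8445 and 7260 CPM in FOXD2 libraries, MT-RNR2 14855 and 16117 against 15895 and 14612), and the mitochondrial share was higher in FOXD2 replicate 2 than in replicate 1.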
